A study of Homo sapiens with 6 samples.

How the data were processed

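RNA-seq libraries from 3 samples of NOZ cells and 3 of NOZ-R cells were compared. NOZ is an established human gallbladder cancer line. Per the labels' protocols, poly-A RNA was selected from total RNA with oligo-dT beads, fragmented, copied with random primers, selected for size and amplified by PCR. No step that marks strand and no molecular identifiers are described there.

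The authors deposited a table of counts per gene, whole numbers that were not normalized, and a table of FPKM values for the same 63140 genes. Reads were processed with fastp version 0.22.0 and the genome build was GRCh38, per the submitters' processing notes. The aligner, the counting tool, its strand setting and the annotation release are not given in the sources used here. In the deposited FPKM table each value equals the count divided by the library's total count and 1 fixed length per gene, so it holds no composition correction. No cell was 0 in 1 table only, and the largest relative spread of the implied length across libraries was 8.10e-14. Of the genes, 20470 carry an Ensembl identifier only, 0 rows name no gene, and 31615 had at least 1 count. Positions and transcript GC content were taken from the GENCODE annotation of GRCh38 in the reference, matched through gene symbols. They were found for 13896 of the 14386 tested genes (positions) and for 96.6% (GC content). The release used by the authors may differ.

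The samples were grouped by their titles. Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr on the group, libraries were scaled with TMM factors (0.954 to 0.961 in NOZ-R, 1.04 to 1.05 in NOZ), and NOZ-R was compared with NOZ by the quasi-likelihood test (glmQLFit and glmQLFTest) with Benjamini-Hochberg adjustment at 0.05. CPM values use the TMM-scaled library sizes. The standard error of a log2 fold change is its size divided by the square root of the F statistic. For genes with few counts in 1 line, such as TRIM29, CCL2 and CD81, it can understate the error. Lists of 697 distinct genes were tested with limma 3.58.1 camera on log2 CPM (prior count 2, preset correlation 0.01), for the 26 of 27 lists with at least 5 tested members, and again with an estimated correlation and with fry, whose p asks whether a list's genes move, on balance, in the same direction. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for annotation and plots.

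The test, the lists, the named genes' rule and the alternatives were fixed before the data were examined. Genes named were the 6 largest increases and the 6 largest decreases among genes with a symbol, an adjusted p below 0.05, a mean of at least 10 CPM and no overlap between the lines, then up to 2 increases and 2 decreases among the members of each list past the test, and always SLC29A1, SLC28A3, DCK, CDA, RRM1, RRM2, ABCB1, ABCC1, ABCG2 and NT5E. Some genes that the rule selects are not reported here. COL1A1, MVP and ABCC3 were named outside the rule, after their values were seen. Alternatives were DESeq2 size factors, upper-quartile factors, library size only, no filter, a filter of 1 CPM in 3 libraries, the Wald test of DESeq2 1.42.0, limma on log2(FPKM + 1) and log2(FPKM + 0.1), the replicate number as a block, a threshold of 0.01, a test against a 2-fold change, and leaving out each library. A correction for GC content (a loess trend per library, span 0.3) and the removal of chromosome medians were added after seeing the data.

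Total counts were 19244923, 17253439 and 14136037 in NOZ replicates 1 to 3 and 18855409, 16954519 and 15661532 in NOZ-R replicates 1 to 3. A gene with no count in NOZ has a floor of 3 counts over the group, 0.0568 CPM. Intervals and floors cover counting error only, since PCR copies are not told apart. Replicates were checked for duplicates. The mean chi-square per gene of replicate pairs lay between 2.26 and 12.7, above the value of about 1 that sampling noise alone gives, and all 6 libraries were kept. Within its line, NOZ replicate 2 stood apart in GC content, with a rank correlation across genes between its deviation and transcript GC of -0.647, against 0.441 and 0.508 for NOZ replicates 1 and 3. Genes that overlap others on the opposite strand, among them DDIT4, CA9, NT5C2 and GINS4, genes that share exons with another gene model, among them RRM2 and AXIN2, and genes with near-identical copies cannot be separated with certainty.

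The scripts were tested on simulated counts for NOZ-R against NOZ over 14386 genes, with 200 changed genes in each of 10 draws. On average 82.2% of log2 changes of 1 were recovered, and 100% of those at 10 CPM or more. For log2 changes of 0.5 the shares were 61.8% and 90.6%. False calls made up 7.04% of calls on average (2.31% to 10.8%), above the nominal 5%, so the adjusted p-values were slightly too small in the simulation. The share of false calls depends on how many genes change. It does not carry over to the real comparison, where 60.2% of the tested genes passed. A planted shift of 1 list and of 1 chromosome was recovered, with 0 other lists called. The simulated genes were drawn independently, so this 0 does not bear on false list calls among correlated genes.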

Results

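RNA-seq was used to compare NOZ-R, a gallbladder cancer line selected for resistance to the nucleoside analogue gemcitabine by stepwise raising of the dose, with NOZ, the established human line it was derived from. Each line was represented by 3 libraries of poly-A RNA. The total count per library lay between 14136037 and 19244923, with similar depth in both lines. Mitochondrial transcripts took 6.23% ± 0.117 of the counts in NOZ and 5.91% ± 0.138 in NOZ-R (SD, n = 3 each). Across the 14386 genes tested, log2 CPM correlated with r of 0.991 to 0.993 between replicates and of 0.922 to 0.926 between the lines. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

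The comparison of NOZ-R with NOZ asked which transcripts differ between the resistant and the parental line. ABCB1, the multidrug efflux pump P-glycoprotein, and TRIM29, a member of the tripartite motif family, rose from a few counts to among the most abundant transcripts. ABCB1 (chromosome 7, 87503633 to 87713323) had 3 counts in all over the NOZ libraries and 12663 CPM ± 506 in NOZ-R (SD, n = 3), a ratio of 222800 with a 95% counting interval of 76240 to 1080000 (edgeR adjusted p = 2.95e-18). TRIM29 (chromosome 11, 120111275 to 120185529) went from 0.310 CPM ± 0.266 to 31807 CPM ± 491 (SD, n = 3 each), a log2 fold change of 16.73 ± 0.136 (SE, edgeR adjusted p = 8.67e-18). This SE is too narrow, since the few NOZ counts had an SD close to their mean. TRIM29 took 3.04% ± 0.0577 of all counts in NOZ-R and ABCB1 took 1.21% ± 0.0444 (SD, n = 3).

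The rule by fitted fold also selected genes with no count in any NOZ library, for which the fold is a lower bound set by 3 counts over the group, so their rank among the increases is not established. LDB2, a LIM domain binding cofactor, was at least 849.8-fold higher in NOZ-R, at 48.3 CPM ± 1.26 (SD, n = 3). The glial glutamate transporter SLC1A3 was at least 839.8-fold higher, the zinc finger gene ZNF385D at least 593.6-fold and the teneurin TENM2 at least 391.1-fold. Among genes with a mean of at least 10 CPM and no overlap between the lines, the largest decrease was in CD81, a tetraspanin, with a log2 fold change of -5.70 ± 0.194 (SE, edgeR adjusted p = 2.97e-11), from 32.0 CPM ± 4.56 to 0.609 CPM ± 0.175 (SD, n = 3 each). CGNL1, which encodes the junction protein paracingulin, changed by -5.12 on the log2 scale, the matrix protein gene SPON1 by -4.96, SYTL5 by -4.58, the neuronal glutamate transporter SLC1A1 by -3.47 and ASB4 by -3.23.

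Of the 14386 genes tested, 4379 were higher and 4284 lower in NOZ-R (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). A change of at least 2-fold was estimated for 1289 of the higher and 1089 of the lower genes, and a test against a 2-fold change itself called 847 and 442. Scaling by library size alone moved the median of all genes by -0.129 on the log2 scale and gave 3316 higher and 5468 lower genes.

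**Figure D1:**
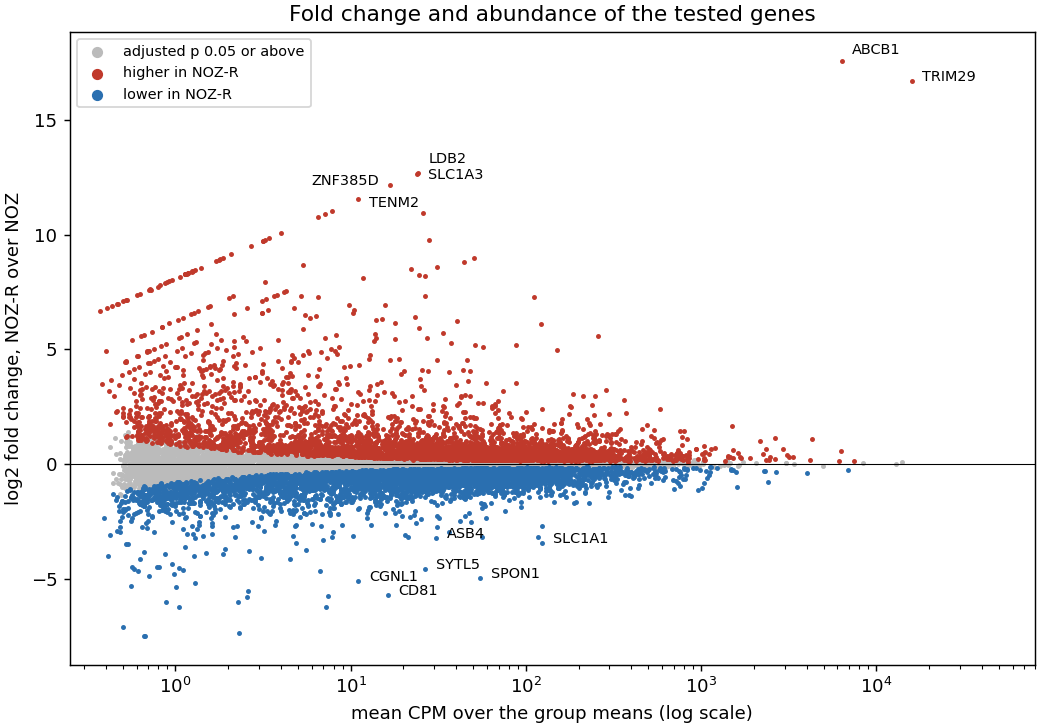
Log2 fold change of NOZ-R over NOZ (y axis) against the mean CPM of both lines (x axis, log scale), 1 point per tested gene, red for higher and blue for lower at an edgeR adjusted p below 0.05 and grey otherwise. ABCB1 and TRIM29 lie apart at the upper right, and the points along the upper left diagonals are genes with 0 or very few counts in NOZ, whose plotted fold depends on the prior count.

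Among the genes that take up gemcitabine and phosphorylate it, the transporter gene SLC29A1 rose while the first kinase of the pathway was close to its parental level. SLC29A1 (chromosome 6, 44219505 to 44234151), which encodes the equilibrative nucleoside transporter ENT1, rose from 21.1 CPM ± 2.20 to 44.1 CPM ± 3.39 (SD, n = 3 each), a log2 fold change of 1.06 ± 0.0933 (SE, edgeR adjusted p = 3.75e-07). SLC29A2, a second equilibrative transporter gene, fell by 0.53 on the log2 scale (edgeR adjusted p = 0.00471). DCK, deoxycytidine kinase (chromosome 4, 70992538 to 71030914), measured 68.7 CPM ± 2.67 in NOZ and 76.7 CPM ± 3.01 in NOZ-R (SD, n = 3 each). Its log2 fold change of 0.16 ± 0.0641 (SE, edgeR adjusted p = 0.0471) lost the call in 13 of 17 alternative settings. The mitochondrial kinase gene DGUOK changed by 0.24 (edgeR adjusted p = 0.0222), a call lost in 7 of 17 settings. The concentrative transporter gene SLC28A3 had 0 counts in NOZ and 5, 2 and 6 counts in the NOZ-R libraries, too few to be tested. Of the 8 tested members of this list, 3 were higher, 1 was lower and 4 did not pass, and adjusted over the list alone 2 were higher and 1 was lower.

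The enzymes that inactivate gemcitabine or are its targets moved mostly upward, by small amounts. Of 14 tested members, 10 were higher, 3 were lower and 1 did not pass, and adjusted over the list alone 10 were higher and 4 lower. SAMHD1, a deoxynucleotide triphosphohydrolase, rose from 55.7 CPM ± 1.30 to 161.0 CPM ± 4.19 (SD, n = 3 each), a log2 fold change of 1.53 ± 0.0590 (SE, edgeR adjusted p = 9.78e-11). The nucleotidase gene NT5C3A rose by 0.87, cytidine deaminase CDA by 0.63 ± 0.105 (SE, edgeR adjusted p = 0.000145) and the ectonucleotidase NT5E by 0.52. The ribonucleotide reductase subunits moved apart, with RRM2 at 0.29 ± 0.0512 and RRM1 at -0.29 ± 0.0535 (SE, edgeR adjusted p = 0.000237 and 0.000385). CTPS2, a CTP synthase, fell by 1.80 on the log2 scale and the nucleotidase NT5C2 fell by 0.31. Both lie on chromosomes whose genes were lower in general, with medians of -0.44 on X (CTPS2) and -0.60 on 10 (NT5C2). Camera called neither this list (adjusted p = 0.186) nor the uptake list (adjusted p = 0.832), whose median of -0.03 and mean of 0.09 differ in sign.

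Of 12 tested efflux genes, 5 were higher, 4 were lower and 3 did not pass, with the same counts adjusted over the list alone. Besides ABCB1, the higher genes were ABCB11, the bile salt export pump (log2 fold change 0.77, from 1.15 CPM to 1.98 CPM, a call lost in 8 of 17 settings), ABCC1, which encodes MRP1 (0.61 ± 0.0563, SE, edgeR adjusted p = 6.59e-07), the major vault protein gene MVP (0.48) and ABCC3 (0.18). ABCC5 fell by 0.79 and ABCA3 by 0.41 on the log2 scale. ABCG2, the breast cancer resistance protein gene, measured 7.96 CPM ± 0.767 in NOZ and 9.42 CPM ± 0.944 in NOZ-R (SD, n = 3 each), a log2 fold change of 0.24 ± 0.130 that did not pass (SE, edgeR adjusted p = 0.122). The median log2 fold change of the list was 0.09, its mean of 1.46 was set by ABCB1, and camera did not call it (adjusted p = 0.832). Across these 3 lists, 26 genes passed the test.

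**Figure D2:**
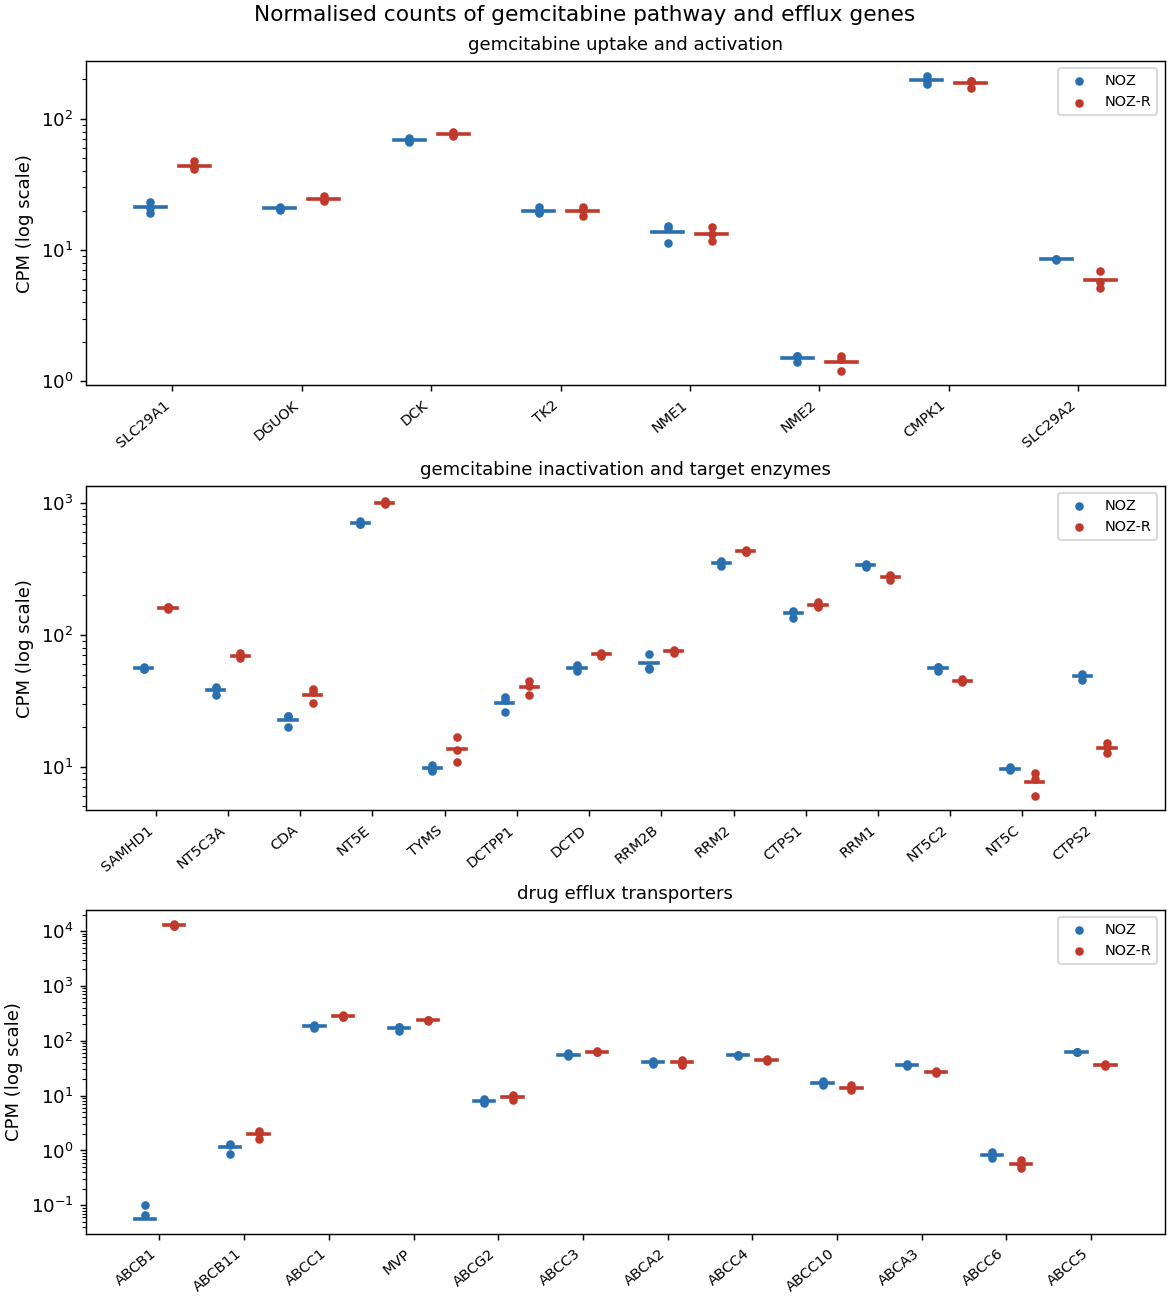
CPM of each library (points, log scale) and the mean of each line (bars) for the tested members of the uptake and activation, inactivation and target, and efflux lists, blue for NOZ and red for NOZ-R, with 3 libraries per line. ABCB1 rises from 0.0559 to 12663 CPM, 1 NOZ library with 0 counts is not drawn for it, and most other genes differ by less than 2-fold.

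Genes induced by type I interferon rose as a group. All 37 tested members were higher, 35 of them at least 2-fold, with a median log2 fold change of 2.56 (camera adjusted p = 8.98e-20, and adjusted p = 0.00998 with an estimated correlation). USP18, a deISGylase, rose by 5.72 ± 0.123 on the log2 scale (SE, edgeR adjusted p = 3.25e-13), from 1.23 CPM ± 0.232 to 65.9 CPM ± 3.15 (SD, n = 3 each), and IFI44L rose by 5.20. All 18 tested genes of MHC class I antigen presentation were higher, with a median of 1.22 (camera adjusted p = 5.65e-09, and adjusted p = 0.0370 with an estimated correlation). The peptide transporter TAP1 rose by 2.54 and HLA-F by 2.43. HLA-F overlaps annotated antisense transcripts and resembles other HLA genes, so its counts are uncertain.

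Of 27 tested genes of NF-kappaB signalling and inflammatory cytokines, 24 were higher and 1 was lower, with a median of 2.16 (camera adjusted p = 7.53e-10, and adjusted p = 0.0237 with an estimated correlation). The chemokine CCL2 rose by 6.57 ± 0.256 on the log2 scale (SE, edgeR adjusted p = 1.12e-10), from 0.204 CPM to 20.5 CPM. The acute phase gene SAA1 had 2 counts over the NOZ libraries and 209 over NOZ-R, a ratio of 112.4 with a 95% counting interval of 30.7 to 934. TNFAIP2 fell by 0.39. The counts of these 3 lists were the same adjusted over the list alone, and these were the 3 lists whose camera calls held with an estimated correlation.

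Genes of the unfolded protein and integrated stress responses were higher in 27 and lower in 2 of 33 cases, with a median of 0.92 (camera adjusted p = 9.30e-08). With an estimated correlation the adjusted p = 0.0565. DDIT4, an inhibitor of mTORC1 signalling, rose by 2.93 and the transcription factor ATF3 by 2.13, while the cystine transporter SLC7A11 fell by 0.49. Of 33 hypoxia and glycolysis genes, 21 were higher and 7 lower, with a median of 0.59 (camera adjusted p = 0.00338, and adjusted p = 0.414 with an estimated correlation). The prolyl hydroxylase EGLN3 rose by 5.13 and carbonic anhydrase CA9 by 3.41, while PDK3 fell by 1.49 and BNIP3 by 1.45, the latter call lost in 1 of 16 settings. Of 25 NRF2 target and glutathione genes, 15 were higher and 6 lower (camera adjusted p = 0.0408, and adjusted p = 0.409 with an estimated correlation). AKR1C3 rose by 2.73 and AKR1B10 by 2.08, both from families of similar sequence, and GSTP1 fell by 0.82. The NRF2 call was lost without NOZ replicate 2 or 3 (adjusted p = 0.0849 and 0.0600) and without NOZ-R replicate 1 or 2 (adjusted p = 0.0658 and 0.0619). It was also lost with the replicate number as a block (camera adjusted p = 0.0608) and after GC correction (camera adjusted p = 0.0947).

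Of 21 genes of mesenchymal transition, 15 were higher and none was lower, with a median of 0.56 (camera adjusted p = 3.85e-05, and adjusted p = 0.118 with an estimated correlation). Thrombospondin THBS1 rose by 5.59 ± 0.0699 (SE, edgeR adjusted p = 1.70e-15), from 10.6 CPM ± 0.451 to 507.8 CPM ± 19.2 (SD, n = 3 each). MMP2 had 3 counts over the NOZ libraries and 51 over NOZ-R. Of 26 YAP and TGF-beta targets, 16 were higher and 2 lower, with CCN2 at 2.04 and CCN1 at 1.74 (camera adjusted p = 0.0113, and adjusted p = 0.134 with an estimated correlation). ANKRD1 fell by 0.42 and TGFBR2 by 0.23. Of 23 epithelial junction and keratin genes, 10 were higher and 6 lower (camera adjusted p = 0.492). E-cadherin CDH1 fell by 1.83 from 1.03 CPM, CLDN4 fell by 0.92, and the splicing regulator ESRP1 rose by 3.78.

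Markers of other cell types and states were measured beside these groups. Of 15 fibroblast markers, 6 had enough counts to be tested. Of these, 4 were higher and none was lower, or 4 and 1 adjusted over the list alone. Their median was 3.27 (camera adjusted p = 0.0200, and adjusted p = 0.246 with an estimated correlation). Setting the genes at 0 in NOZ, POSTN and FAP, to their bounds could not change this median, since they remained the highest members. Among untested markers, COL1A2 and THY1 were near 0 in both lines, while DCN had 19, 12 and 6 counts in NOZ-R. POSTN was at least 63.4-fold higher and FAP at least 18.3-fold higher, whereas COL1A1 had a log2 fold change of -0.54 (edgeR adjusted p = 0.0548). Of 18 leukocyte and endothelial markers, 4 had enough counts to be tested, too few for camera. Of these, 3 were higher, among them PECAM1 at 2.29 and CSF1R at 1.85, the latter from 12, 8 and 7 counts to 37, 21 and 33. Among untested markers, CDH5 had 13, 8 and 8 counts in NOZ and 7, 11 and 2 in NOZ-R. PTPRC was lower in NOZ-R, and VWF and KDR had at most 2 counts in any library. Of 25 squamous lineage genes, 10 had enough counts to be tested, with 7 higher and 2 lower (camera adjusted p = 0.0340, and adjusted p = 0.197 with an estimated correlation). The call was also lost after GC correction. Of the untested members, IVL, SPRR3 and S100A8 had 0 counts in every library, and KRT13 had at most 14. The desmosomal cadherin DSC3 rose by 5.36 and keratin KRT14 by 5.27, while KRT6A fell by 1.67 and PKP1 by 0.86. Keratin genes have near-identical copies, so their counts are uncertain. Of 31 biliary and gastrointestinal genes, 14 had enough counts to be tested, with 7 higher and 6 lower. There was no camera call (adjusted p = 0.832), and the median was 0.03 although the test pointed downward. The trefoil factors TFF3 and TFF2 rose by 3.30 and 2.87, while CEACAM5 fell by 3.17, from 209.9 CPM ± 5.62 to 23.3 CPM ± 2.16 (SD, n = 3 each), and KRT20 fell by 1.90.

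Genes of G2 and mitosis were the 1 list called lower. Of 34 tested members, 25 were lower and 3 higher, or 25 and 4 adjusted over the list alone, with a median of -0.35 (camera adjusted p = 0.00137, and adjusted p = 0.158 with an estimated correlation). The kinetochore gene CENPF fell by 0.97 on the log2 scale and HMMR by 0.96. CENPF varied more in NOZ, with 313.5 CPM ± 73.0, than in NOZ-R, with 160.0 CPM ± 10.8 (SD, n = 3 each). BIRC5 and CDC20 rose by 0.21 each, calls that were each lost in 5 of 17 settings. The 38 S phase and replication genes went both ways, with 14 higher and 13 lower (15 and 13 adjusted over the list alone, camera adjusted p = 0.853). MCM6 rose by 0.72 and MCM3 by 0.58, while GINS4 fell by 0.80 and POLA1 by 0.78. The median of chromosome X, which holds POLA1, was -0.44, and that of chromosome 6, which holds MCM3, was 0.33. Of 45 DNA repair and replication stress genes, 17 were lower and 8 higher (camera adjusted p = 0.186). CLSPN, a checkpoint mediator, rose by 0.38, a call lost in 4 of 17 settings, and XPA fell by 1.23 and the alkyl transferase MGMT by 1.19. The medians of chromosome 9, which holds XPA, and chromosome 10, which holds MGMT, were -0.64 and -0.60. Of 24 p53 target genes, 10 were higher and 4 lower (10 and 5 adjusted over the list alone, camera adjusted p = 0.581), with the cell cycle inhibitor CDKN1A at 1.59, PMAIP1 at 1.31, CCNG1 at -1.13 and TP53INP1 at -0.94.

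The remaining lists had no camera call. Of 30 cell death regulators, 14 were higher and 4 lower (camera adjusted p = 0.0710), with TNFSF10, the death ligand TRAIL, at 5.02, BIRC3 at 2.36, BMF at -2.11 and APAF1 at -0.65. Of 32 cholesterol and fatty acid genes, 9 were higher and 10 lower (camera adjusted p = 0.832), with STARD4 at 2.34, SCD at -0.97 and INSIG1 at -0.97. Of 15 stem cell associated genes, 7 were higher and 5 lower (camera adjusted p = 0.915, median 0.01, mean -0.07, camera direction up), with CD24 at 1.31, POU5F1 at 0.88, a call lost in 11 of 17 settings, NES at -1.69 and SOX4 at -1.39. MAPK feedback genes and EGFR ligands were higher in 13 and lower in 12 of 28 cases (camera adjusted p = 0.832), with BTC at 2.26, NRG1 at 1.24, ERBB3 at -1.65 and DUSP5 at -1.57. Of 22 WNT and NOTCH genes, 8 were higher and 10 lower (8 and 11 adjusted over the list alone, camera adjusted p = 0.757), with FZD7 at 2.08, AXIN2 at 1.5, NKD1 at -2.05 and WNT10B at -1.70. The 13 mitochondrially encoded genes were split, 4 higher and 5 lower (camera adjusted p = 0.853, median 0.02, mean -0.06), with MT-ND1 and MT-ND5 at 0.31 each, MT-ND3 at -0.57 and MT-CYB at -0.37, calls lost in 3, 2, 1 and 1 of 17 settings. Of 21 immediate early and heat shock genes, 13 were higher and 5 lower (13 and 7 adjusted over the list alone, camera adjusted p = 0.173), with EGR2 at 1.55, EGR3 at -1.57 and JUND at -0.76. For 19 of the 27 lists the counts adjusted over the list alone were the same as those adjusted over all genes.

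**Figure D3:**
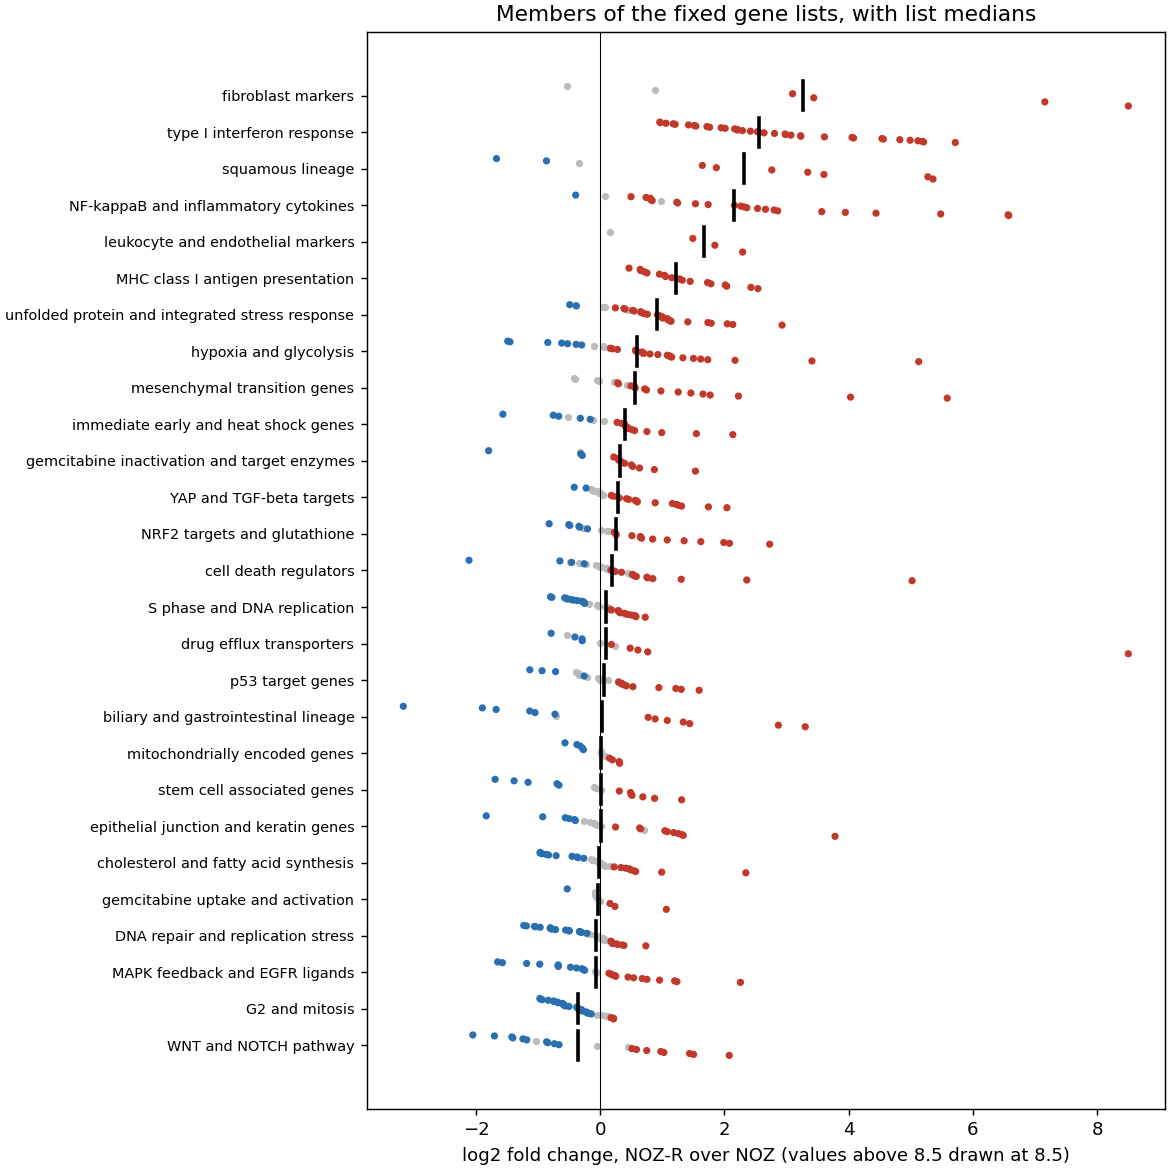
Log2 fold change of NOZ-R over NOZ (x axis) for each tested member (points) of the 27 fixed lists (rows), red for higher, blue for lower and grey for an edgeR adjusted p of 0.05 or above, with the list median as a black bar. All 37 interferon genes lie to the right of 0, and 2 members above 8.5, ABCB1 and POSTN, are drawn at 8.5.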

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

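The GC correction and the removal of chromosome medians were chosen after seeing the data. So were the settings of the neighbour windows and of the count over the uptake, inactivation and efflux lists. Of the 113 tested genes that the naming rule selects, none reversed in any of 17 settings and 14 lost or gained a call in at least 1. Leaving out libraries gave 4018 to 4634 higher and 3833 to 4328 lower genes. There was no sign that the replicate numbers pair the libraries. Deviations of same-numbered libraries correlated at 0.0682, -0.0224 and -0.0365, and 1 of the 3 NOZ libraries correlated best with its own number. With 3 libraries per line, a shared batch cannot be excluded this way. With the replicate number as a block, 4324 genes were higher and 4180 lower, 1280 and 1080 at least 2-fold, and 10 lists were called. Across the uptake, inactivation and efflux lists, 24 genes passed. The NRF2 list lost its call (camera adjusted p = 0.0608), as did 2 named genes, DCK and POU5F1, and no other list or named gene changed.

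On log2(FPKM + 1), which lowers the fold of weakly expressed genes by its construction, 428 and 374 genes passed the 2-fold limit. With no filter these were 436 and 394, with 2901 higher genes in all and 17 genes passing across the uptake, inactivation and efflux lists. The test against a 2-fold change gave 847 and 442, a stricter question by construction. Other causes were not tested. Small changes in genes of low count are the most likely to be missed.

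Camera called 11 lists. With an estimated correlation, 3 were called, and the adjusted p was 0.158 for G2 and mitosis, 0.118 mesenchymal, 0.409 NRF2, 0.414 hypoxia, 0.0565 stress response, 0.134 YAP, 0.197 squamous and 0.246 fibroblast. Fry, which asks another question, called 22, adding uptake (0.0224), inactivation (0.000780), efflux (0.000542), DNA repair (0.000837), p53 (0.000300), epithelial (0.00376), cell death (0.000201), MAPK (0.000336), biliary (0.000158) and immediate early genes (0.000200), and stem cell genes in the opposite direction (0.0121). After GC correction 9 lists were called, with NRF2 at 0.0947 and squamous at 0.0511. With chromosome medians removed DNA repair (0.0322) and immediate early genes (0.0302) were also called. With no filter cell death was called (0.0116). Lists without a call that changed direction were S phase (0.938 with library size only, 0.921 on FPKM), biliary (0.938, 0.921, and 0.563 with no filter), uptake (0.703 with chromosome medians removed) and mitochondrial genes (0.835 after GC correction). Leaving out libraries gave ranges of 0.0270 to 0.0849 for NRF2, lost without NOZ replicate 2 (0.0849) or 3 (0.0600) and without NOZ-R replicate 1 (0.0658) or 2 (0.0619), 0.0454 to 0.0903 for cell death, called without NOZ replicate 1 (0.0468) and without NOZ-R replicate 3 (0.0454), and 0.840 to 0.9946 for stem cell and 0.860 to 0.988 for biliary genes, neither called. The direction changed for both without NOZ replicate 1 (0.922), and for biliary genes also without NOZ replicate 3 (0.987) and without NOZ-R replicate 2 (0.988). Windows of neighbouring genes beyond the 95% limit of the shuffles numbered 11 by the mean and 44 by the median. The cause of the other changes was not tested.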

Other observations

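All tests in this part except the splits of the libraries and the windows by their mean were chosen after the result was seen, as were the genes named here other than ABCB1, TRIM29 and CSF1R. ABCB1 was 1 of 17 genes with at most 3 counts over NOZ and at least 100 in each NOZ-R library, and 0 genes showed the opposite. Among them were the gap junction gene GJA1, at 52.0 CPM ± 0.747 in NOZ-R and a ratio of 2747 (95% counting interval 492.7 to 108600), VAV3, a guanine nucleotide exchange factor, at 55.6 CPM ± 3.18, the transcription factor MEF2C, at 10.4 CPM ± 0.190, and the adhesion molecule VCAM1, at 8.02 CPM ± 1.05 (SD, n = 3 each). VCAM1 was at least 141.2-fold higher. The guanylate binding protein genes GBP1 and GBP4 rose by 8.82 and 8.61 on the log2 scale. On chromosome 9, the neighbouring genes CDKN2A, CDKN2B and MTAP fell, with log2 fold changes of -1.09, -1.91 and -1.11 (edgeR adjusted p = 1.83e-08, 8.56e-10 and 4.15e-09). Part of these falls was shared along the chromosome, whose median was -0.64, with 412 of 552 tested genes lower.

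In 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, 8663 genes passed edgeR's test, against a highest other value of 0. At an unadjusted p below 0.05 these were 9218 genes in the real split and 40 to 175 in the others. In 1 of 10, again the real one, 2378 genes changed at least 2-fold, against 0. For the gene lists the real split called 11, and 1 of 10 splits reached that number, against a highest other value of 8. The 10 splits are too few for a share under 0.05. The other splits mix the lines, which puts the difference between the lines inside each group. Their 0 gene calls were thus nearly fixed by construction and carry no weight. These mixed splits called 5 to 8 lists with the preset correlation. Part of the difference between the lines also stays between their groups. Their list calls thus neither measure false calls nor lend weight to the 11.

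ABCB1 and TRIM29 were very high in NOZ-R. A gain of the chromosomal neighbourhood would raise the genes around them, but the 10 nearest tested genes had a median log2 fold change of -0.59 for ABCB1, with 7 lower and 0 higher, and of 0.16 for TRIM29, with 5 higher and 2 lower. The low level around ABCB1 was not local. Windows of 50 tested genes on chromosome 7 from 77696443 to 155781485 had median log2 fold changes between -0.65 and -0.23. Reads of the paralog ABCB4 as the source are argued against by the highest ABCB4 count in a NOZ-R library, 9. A gain limited to the gene itself, a change of promoter, or an introduced construct may each account for such levels and stay open, untested, because the table holds 1 count per gene and no DNA was analysed here. The selection with gemcitabine that the design names also stays open, as untested.

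Genes of chromosomes 9 and 10 were lower together in NOZ-R, with a median log2 fold change of -0.61 over 1104 tested genes, 803 of them lower and 95 higher. GC content bias is argued against by the GC correction, after which their median still lay at -0.594 relative to all genes. Of the tested genes of both chromosomes, 84.9% lay below the median of all genes, so the shift was broad. This adds no separate test against a few strongly changed genes, since a median this low already places most genes below. Fewer copies of these chromosomes are a candidate explanation: 0 of the 22 windows of 50 genes had a median at or above that of all genes, the highest being -0.37, but by the planned window mean 1 of them, on chromosome 10 from 45615501 to 63521850, lay 0.34 above all genes, and 4 of the 22 lay beyond the shuffles, against 20 by the median. Beyond the shuffles means beyond the 95% quantile of the largest window deviation in each of 1000 shuffles of the genes. Of 265 windows, 11 lay beyond this limit by the mean, 5 higher and 6 lower, and 44 by the median with its own limit. Chromosomes X, 13 and 7 had medians of -0.44, -0.38 and -0.30 and chromosome 6 of 0.33. Changes of single genes on these chromosomes may in part be the shared shift. Among such genes were XPA, MGMT, NT5C2, BNIP3, CTPS2, POLA1 and PDK3, which fell, and SLC29A1 and MCM3, which rose. A stock of different origin or drift in culture stays open, untested, as no DNA was analysed here.

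Interferon-stimulated genes were higher in NOZ-R, in 37 of 37 cases. Leukocytes in the cultures are argued against by 11 leukocyte markers, whose summed CPM was 1.31 times as high in NOZ-R (7.06 ± 0.481 against 5.39 ± 1.39, SD, n = 3 each). The most abundant of them, CD14, did not pass the test, and PTPRC stood at 4, 2 and 5 counts against 28, 14 and 7 in NOZ, although CSF1R and LYZ were higher. GC content bias is argued against by the median of 2.51 after GC correction. An interferon-like state of the selected cells, or culture conditions, may account for it and stay open, untested. Of the interferon genes, IFNB1 went from 0 to 3 counts over the libraries of a line, IFNA1 from 15 to 6 and IFNE from 340 to 117. IFNL1 went from 4 to 5 counts, IFNL2 from 0 to 2 and IFNL3 from 2 to 0, and IFNG and IFNK had 0 in both lines.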
